A study of Arabidopsis thaliana with 24 samples.

How the data were processed

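The series holds 24 RNA sequencing libraries from 2-week-old Arabidopsis thaliana seedlings of the Col-0 background, wild type (WT) or overexpressing the long noncoding RNA ELENA1 (OX). Seedlings were moved from solid to liquid medium with elf18 at 5 µM, per the labels' protocols, and sampled at 0 h, 1 h, 6 h and 12 h. The peptide elf18 is the N-terminal epitope of bacterial elongation factor Tu that the receptor kinase EFR perceives. The labels give 3 biological replicates for each of the 8 groups of genotype and time. There is no group moved to liquid medium without peptide, so the treatment, the transfer and the time of day cannot be told apart in any comparison with 0 h. Polyadenylated RNA was made into strand-specific libraries and sequenced as single reads, and the replicates of a condition were pooled for sequencing, per the labels' protocols.

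Read counts per locus in 24 columns were deposited by the authors, with 1 column per library, per the file headers. The values were whole numbers with different column totals. FPKM values were deposited by the authors in 8 columns, 1 for each group, per the file headers, so they carry no spread between replicates. TopHat2 2.0.8, Cufflinks 2.1.1, Cuffdiff, DESeq2 and the build TAIR10 are named, with no role or order, per the submitters' processing notes. The counting tool and its strand setting are not given in the sources used here. Reads shared between close paralogs (light-harvesting, small heat shock, cysteine-rich receptor-like kinase and PAL genes, for example), overlapping genes such as the upstream reading frame AT1G73602, or antisense partners may therefore be split in ways the counts do not show. Values of single members of those families are uncertain.

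Of the loci counted, 21330 matched a locus of the TAIR10.1 annotation, and 77 did not. The annotation was used for names, chromosome number, spliced transcript lengths and the order of neighbouring loci. No coordinates are printed, because the build named by the submitters and the annotation used here differ in name. There were 0 plastid or mitochondrial loci among the counts. In 4 cases the gene symbol had been turned into a date, so the locus identifier was used as the key throughout. ELENA1 itself (AT4G16355) was not analysed here.

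The counts were tested with edgeR 4.0.16 in R 4.3.3. All 24 libraries entered a single quasi-likelihood fit with 8 group means, so that every comparison shared an estimate of the spread. Library sizes were scaled by TMM, and filterByExpr with a minimum count of 10 left 21015 genes. The Benjamini-Hochberg adjusted p had to be under 0.05. Comparisons were OX against WT at each of 4 times, each later time against 0 h within each genotype, and the difference between the genotypes in each of these 3 responses (interaction). Fold changes are log2, with the standard error (SE) from the fit, and levels are counts scaled to library size (CPM) with the standard deviation (SD) over replicates. Every adjusted p of a gene is from edgeR's quasi-likelihood test unless DESeq2 is named.

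The 24 gene lists were fixed before the data were examined, as were the tests, the first set of alternatives and the rule for named genes. They are early elf18/flg22 marker genes, pattern recognition and early signalling components, salicylic acid and systemic acquired resistance, jasmonate and wound response, ethylene synthesis and response, tryptophan-derived defence compounds, aliphatic glucosinolate synthesis, phenylpropanoid and monolignol synthesis, and flavonoid and anthocyanin synthesis. Further lists are nuclear photosynthesis genes, circadian clock and time-of-day genes, auxin response and transport, cell cycle, expansins, endoplasmic reticulum protein folding and heat shock. The last are low-oxygen response, abscisic acid and osmotic response, Mediator subunits, intracellular immune receptors, cysteine-rich receptor-like kinases, and markers of root, stomatal lineage, and shoot meristem and epidermis. They name 474 members, of which 468 were in the count table. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 24 lists within a comparison. The test was repeated with the correlation estimated for each list. For each list the number of members that passed is given over all genes tested and adjusted over the list alone. Genes are named by a rule: the loci next to ELENA1, with 3 on each side, and PR1 in every comparison. From each list described come up to 4 members with the smallest adjusted p, plus any needed to show the opposite direction. To these are added the 5 largest positive and 5 largest negative fold changes among genes that passed, with a mean log2 CPM of 1 or more and no overlap between the libraries of the groups compared.

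Alternatives chosen in advance were DESeq2 1.42.0, RLE size factors, no filter, only the libraries of the groups compared, the replicate number as a block, leaving out each library in turn, an estimated correlation for the lists, and tests of the FPKM values. Chosen after seeing the data were removal of each library's trend with transcript length, leaving out 3 libraries with a steep such trend, and thinning all libraries to the smallest total. Lengths were known for 20956 genes, or 99.7% of those tested. Log2 ratios of the deposited FPKM, with a pseudocount of 1, correlated with the fitted fold changes across 18984 genes with r from 0.944 to 0.981. Genes are not independent replicates, so this r only compares both kinds of value.

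Replicates were compared before they were averaged. Over the 24 pairs within groups, the chi-square per degree of freedom of the counts lay between 1.62 and 52.4 and 0 columns were identical, so each library was used as 1 replicate. The fit was tested on simulated counts for the OX against WT comparison at 0 h, over 20984 genes: 74.6% of genes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 5.67% of the calls were false. For the interaction at 1 h, the simulated recovery was 28.4%, 85.1% and 100%, with 6.58% of the calls false. Of interactions simulated at 1.5-fold, 47.8% were recovered at 6 h and 50.7% at 12 h. Over all comparisons the false share with edgeR ran from 2.21% (OX at 6 h against 0 h) to 8.12% (OX at 12 h against 0 h). With DESeq2 it was 7.18% for WT at 1 h against 0 h and 15.17% for the interaction at 1 h. Few genes were changed, in both directions and with the spread of the fit itself. Scaling with many changed genes and batches were therefore not tested.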

Results

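Polyadenylated RNA from seedlings of 2 genotypes, WT and the ELENA1 overexpressor OX, was sequenced at 0 h, 1 h, 6 h and 12 h of elf18 treatment, with 3 biological replicates in each of the 8 groups and 24 libraries in all. Total counts per library ran from 18767661 to 85230211. Replicate 3 of every group lay at the low end, between 18767661 and 23645600. The 10 most abundant genes took 3.01 to 5.93% of the counts of a library. Of the loci counted, 21015 had enough counts to be tested and 19 had no count in any library. The first principal component held 48.3% of the variance and the second 29.7%. The median SD of log2 CPM within a group was 0.132, 0.118, 0.108 and 0.125 in WT at the 4 times and 0.096, 0.149, 0.159 and 0.088 in OX. The libraries OX 1 h replicate 1, OX 6 h replicate 1 and WT 12 h replicate 3 stood apart by counts that fell more steeply with transcript length than in the others.

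The overexpressed locus was considered first. ELENA1 lies on chromosome 4 and was not analysed here, so the overexpression named in the labels is not checked by these values. Among its neighbours, SPK1 differed between OX and WT by log2 fold changes of -0.06, -0.12, -0.14 and 0.15 at the 4 times, and the calcium sensor gene CBL6 by -0.08, 0.25, 0.02 and 0.12. AT4G16360 differed by -0.03, 0.03, -0.06 and -0.02, AT4G16380 by -0.12, -0.25, -0.23 and -0.11, and AT4G16330 by 0.31, -0.24, -0.12 and 0.15. None of these 5 neighbours passed the edgeR test at any of the 4 times with the settings fixed in advance. AT4G16330 at 0 h was at the threshold, with an adjusted p of 0.05 and a range over the alternatives from 0.019 to 0.2. OPT3, an oligopeptide transporter gene that acts in iron distribution, was higher in OX at 1 h (0.44 ± 0.09 SE, n = 3, adjusted p = 0.0042). It was lower at 12 h (-0.40 ± 0.09 SE, n = 3, adjusted p = 0.02). That OPT3 call did not pass without WT 12 h replicate 3 (adjusted p = 0.12), OX 12 h replicate 1 (0.11) or OX 12 h replicate 3 (0.082), within a range of 0.0011 to 0.12 over the alternatives.

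PR1, whose product is secreted and whose transcript marks the salicylic acid response, was higher in OX than in WT at all 4 times. At 0 h PR1 stood at 61.89 ± 26 CPM in OX and 30.04 ± 4.13 in WT (SD, n = 3), a log2 fold change of 1.03 ± 0.28 (SE, adjusted p = 0.013). In WT the PR1 level fell to 8.9 ± 3.08 CPM at 1 h and 6.399 ± 1.1 at 6 h and stood at 36.57 ± 5.13 at 12 h (SD, n = 3). In OX it was 71.88 ± 23.2, 54.46 ± 14.6 and 157.7 ± 30.5 CPM at those times (SD, n = 3). The OX to WT difference in PR1 was then 3.00 ± 0.31, 3.12 ± 0.31 and 2.11 ± 0.28 (SE), with adjusted p = 3.1e-06, 2.4e-06 and 0.00025. Against 0 h, PR1 changed by -1.74 ± 0.30 and -2.26 ± 0.31 in WT at 1 h and 6 h (SE, adjusted p = 2.7e-05 and 1.5e-06), and by 1.36 ± 0.27 in OX at 12 h (adjusted p = 0.00014). The change of PR1 was 0.28 in WT at 12 h (adjusted p = 0.38), and 0.22 and -0.17 in OX at 1 h and 6 h (adjusted p = 0.48 and 0.61). The response of PR1 differed between the genotypes by 1.96 ± 0.40 at 1 h and 2.09 ± 0.41 at 6 h (SE, adjusted p = 0.0023 and 0.0027), and by 1.08 at 12 h (adjusted p = 0.11). The PR1 call at 0 h did not pass without WT 0 h replicate 2 (0.94, adjusted p = 0.072), without OX 0 h replicate 3 (0.72, adjusted p = 0.12) or with the libraries of 0 h alone (adjusted p = 0.059). Its range over the alternatives was 0.0016 to 0.12. With length correction the difference between the 12 h responses of PR1 was 1.21 (adjusted p = 0.039, range 0.039 to 0.22).

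**Figure D1:**
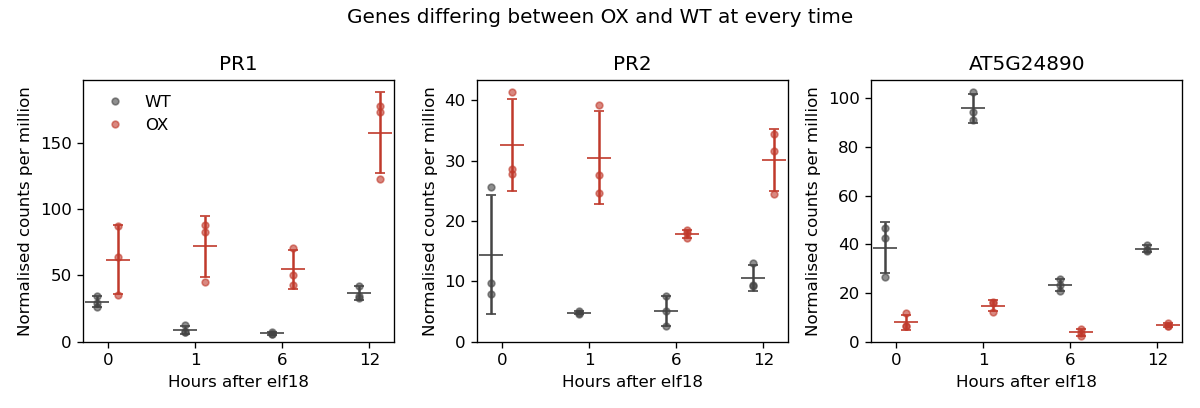
CPM of PR1, PR2 and AT5G24890 in each library (points) by time after elf18 in hours, with the mean and SD of the 3 replicates of WT and OX. The mean of PR1 stood at 30.04 CPM in WT and 61.89 CPM in OX at 0 h and at 36.57 and 157.7 CPM at 12 h, while the mean of AT5G24890 was lower in OX at each time.

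The comparison of OX with WT at 0 h asked how the overexpressor differed before the peptide. Most genes of the heat shock list were lower in OX, and most of the low-oxygen list were higher. HSFA2, a heat shock transcription factor gene, stood at 1.557 ± 0.334 CPM in OX and 16.85 ± 5.28 in WT (SD, n = 3), a log2 fold change of -3.39 ± 0.21 (SE, adjusted p = 1.1e-09). The chaperone genes HSP17.6A (-3.15 ± 0.31), HSP17.6II (-3.11 ± 0.30), AT1G53540 (-2.89 ± 0.29) and HSP101 (-2.35 ± 0.20) were lower too (SE, n = 3), with adjusted p from 4.8e-08 to 4.9e-07. PDC1, for pyruvate decarboxylase of ethanol fermentation, was at 54.53 ± 12 CPM in OX and 8.88 ± 3.7 in WT (SD, n = 3). The plant cysteine oxidase genes PCO1 and PCO2 were higher by 2.17 ± 0.17 and 2.00 ± 0.16 (SE, adjusted p = 2.5e-08 for both). In the heat shock list 0 members were higher and 9 of 12 lower (0 and 9 adjusted over the list alone), with a median of -2.09 (camera adjusted p = 4.4e-14, adjusted p = 0.019 with an estimated correlation). In the low-oxygen list 10 of 16 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 3.1e-07, adjusted p = 0.019 with an estimated correlation). The lower member was HRE2, for an ethylene response factor, at -0.72 ± 0.19 (SE, adjusted p = 0.012). HRE2 did not pass without WT 0 h replicate 2 (adjusted p = 0.093), WT 0 h replicate 3 (0.052) or OX 0 h replicate 1 (0.1), within a range of 0.00037 to 0.14.

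Defence and hormone genes differed in both directions at 0 h. Among salicylic acid and systemic acquired resistance genes, 10 of 32 were higher in OX and 1 lower (13 and 1 adjusted over the list alone). DLO1 and DMR6, whose products hydroxylate salicylic acid, were higher by 1.85 ± 0.17 and 0.96 ± 0.11 (SE, n = 3, adjusted p = 1.5e-07 and 3.3e-06). Camera gave an adjusted p of 1.3e-05 for this list, and adjusted p = 0.22 with an estimated correlation. Of 27 jasmonate and wound response genes 11 were lower and 1 higher (14 and 3 adjusted over the list alone). The repressor gene JAZ6 was lower, with a log2 fold change of -0.78 ± 0.11, as were the transcription factor gene MYC2 at -0.73 ± 0.11 and VSP2 at -1.42 ± 0.21 (SE). The list had a camera adjusted p of 5.4e-06, and adjusted p = 0.29 with an estimated correlation. Lower members were also counted for expansins, which loosen cell walls (5 of 9, 7 adjusted over the list alone), and aliphatic glucosinolate synthesis (4 of 15, 10 adjusted over the list alone). So they were for abscisic acid and osmotic response (8 of 20, 11 adjusted over the list alone) and flavonoid synthesis (4 of 16, 4 adjusted over the list alone). These 4 lists had 0 higher members over all genes, and camera adjusted p values of 2.9e-06, 3.5e-05, 0.00013 and 0.00047. In the same order they had adjusted p = 0.21, 0.28, 0.069 and 0.32 with an estimated correlation. Examples are EXPA5 (-1.07 ± 0.10), MYB29 (-0.90 ± 0.16), the phosphatase gene ABI2 (-0.99 ± 0.13) and MYB12 (-1.13 ± 0.20). Of 33 early marker genes 15 were lower and 6 higher (16 and 9 adjusted over the list alone). Among the lower ones were the zinc finger gene ZAT12 at -2.28 ± 0.18 and WRKY40 at -1.21 ± 0.15 (SE, adjusted p = 2.5e-08 and 5e-06). Of 30 tryptophan-derived defence genes 7 were lower and 2 higher (10 and 4 adjusted over the list alone). Both lists had a camera adjusted p of 0.0037, and adjusted p = 0.63 with an estimated correlation. Neither passed without WT 0 h replicate 1 (0.18 and 0.16).

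In all, 3072 genes differed at 0 h, 1619 higher and 1453 lower in OX, of which 467 changed at least 2-fold. Rankings here and in the comparisons that follow are among genes with a mean log2 CPM of 1 or more and no overlap between the groups' libraries (for interactions, on abundance alone). The largest increases were in HRA1, a repressor of the low-oxygen response (2.62 ± 0.42), AT4G33560 (2.61 ± 0.21), PDC1 (2.58 ± 0.22), the asparagine synthetase gene ASN1 (2.50 ± 0.27) and LBD41 (2.41 ± 0.41, SE), with adjusted p from 2.6e-08 to 0.00024. AT2G28210, for an alpha carbonic anhydrase, was among the largest decreases (-2.89 ± 0.28, adjusted p = 3.1e-07). LBD41 was uneven within WT, at 62.34, 6.833 and 17.02 CPM in the 3 replicates. With only the libraries of 0 h in the fit LBD41 did not pass (adjusted p = 0.056, range 4.4e-10 to 0.056), 1889 genes were called and 41.6% of them were higher, against 52.7% with all libraries. Without WT 0 h replicate 2, 1825 genes were called.

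**Figure D2:**
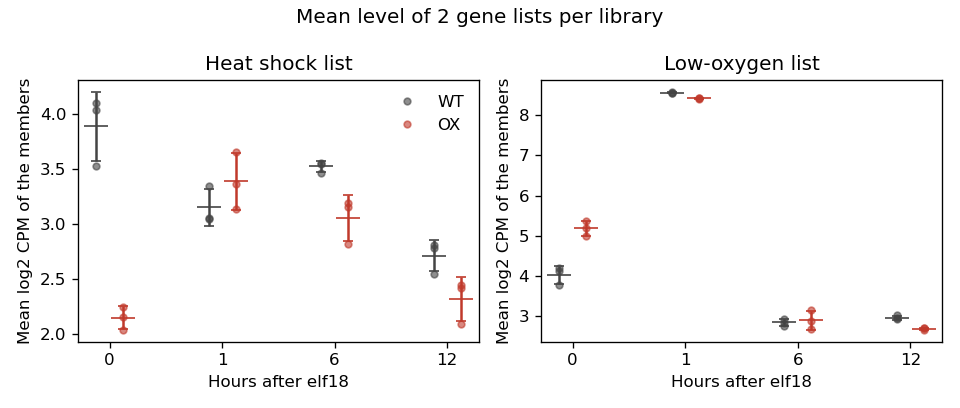
Mean log2 CPM over the heat shock list and over the low-oxygen list in each library, by time after elf18 in hours, with WT and OX as separate points. At 0 h the heat shock mean lay between 2.04 and 2.25 in OX and between 3.53 and 4.1 in WT, and the low-oxygen mean between 4.99 and 5.37 in OX and between 3.78 and 4.19 in WT.

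At 1 h the comparison asked how OX differed from WT early in the response. Among the genes that passed, those of salicylic acid were higher in OX, and those of jasmonate and ethylene more often lower. Of 32 salicylic acid genes 10 were higher and 0 lower (13 and 1 adjusted over the list alone). DLO1 was at 1.75 ± 0.21 and NIMIN1, whose product binds the receptor NPR1, at 1.16 ± 0.19 (SE, n = 3, adjusted p = 1.7e-05 and 5e-04). The glucanase gene PR2 was at 30.51 ± 7.66 CPM in OX and 4.829 ± 0.287 in WT (SD, n = 3), a log2 fold change of 2.64 ± 0.36 (SE, adjusted p = 7.6e-05). Of 27 jasmonate genes 7 were lower and 2 higher (14 and 2 adjusted over the list alone), including JAZ10 (-1.09 ± 0.19) and MYC2 (-0.59 ± 0.10) among the lower. Of 16 ethylene genes 4 were lower and 0 higher (8 and 0 adjusted over the list alone), including ERF1 (-1.16 ± 0.14) and the receptor gene ETR2 (-0.48 ± 0.08). Of 20 abscisic acid and osmotic response genes 4 were higher and 2 lower (8 and 4 adjusted over the list alone). The cold and osmotic stress genes KIN1 and KIN2 were higher by 1.69 ± 0.15 and 1.17 ± 0.15 (SE, adjusted p = 6.2e-07 and 3.6e-05). ABF3 and RD26 were lower, at -0.39 ± 0.11 and -0.41 ± 0.12 (SE, adjusted p = 0.04 and 0.048). The camera adjusted p of that list was 0.028, and adjusted p = 0.45 with an estimated correlation. Camera adjusted p values were 8.9e-07 for salicylic acid, 0.00014 for jasmonate and 0.00024 for ethylene, and in that order adjusted p = 0.27, 0.45 and 0.27 with an estimated correlation. Of 26 auxin genes 5 were higher and 0 lower (7 and 0 adjusted over the list alone), with the carrier genes LAX3 at 0.48 ± 0.07 and PIN7 at 0.50 ± 0.08 (SE). Of 9 expansins 3 were higher and 0 lower (3 and 0 adjusted over the list alone). Their camera adjusted p values were 0.0036 and 0.0034, and both had adjusted p = 0.45 with an estimated correlation.

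A total of 1197 genes differed at 1 h, 587 higher and 610 lower in OX, with 183 changed at least 2-fold. Within the limits on abundance and overlap, the largest increases besides PR1 and PR2 were in the berberine bridge enzyme gene AT1G26390 (3.02 ± 0.32), PCR1 (2.35 ± 0.30) and PCC1 (2.31 ± 0.26, SE), with adjusted p from 5e-06 to 2.8e-05. The largest decreases within these limits were in AT5G24890, of unknown function (-2.68 ± 0.21, adjusted p = 8.2e-08), the subtilase gene AT5G58840 (-1.87 ± 0.27), the peroxidase gene AT3G03670 (-1.72 ± 0.33), AT2G28210 (-1.52 ± 0.27) and the beta-glucosidase gene DIN2 (-1.51 ± 0.19, SE). The count was 472 without OX 1 h replicate 1, 736 without WT 1 h replicate 1 and 648 without WT 1 h replicate 2. It was 612 without the 3 libraries of steep length trend and 502 with the libraries of 1 h alone.

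At 6 h fewer genes differed, and defence genes were again among those higher in OX. PCR1 was higher by 3.03 ± 0.34, LURP1 by 2.40 ± 0.30, AT1G26390 by 2.15 ± 0.26 and the dioxygenase gene ARD3 by 2.09 ± 0.28 (SE, n = 3), with adjusted p from 1.9e-05 to 0.00014. Of 32 salicylic acid genes 6 were higher and 0 lower (9 and 0 adjusted over the list alone). ALD1, needed to make pipecolic acid, was at 1.93 ± 0.26, DLO1 at 1.79 ± 0.17 and DMR6 at 0.84 ± 0.12 (SE, adjusted p = 0.00014, 2.3e-06 and 0.00018). The camera adjusted p of this list was 9.1e-08, and adjusted p = 0.21 with an estimated correlation. Of 17 phenylpropanoid genes 3 were lower and 0 higher (11 and 0 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 1.1e-10, adjusted p = 0.18 with an estimated correlation). Of 33 early marker genes 1 was lower, PHI-1 at -0.77 ± 0.14 (SE, adjusted p = 0.0052), and 0 higher (11 and 0 adjusted over the list alone, camera adjusted p = 4e-06, adjusted p = 0.66 with an estimated correlation). KIN1 was higher by 1.2 ± 0.17 (SE, adjusted p = 0.00021). In its list, abscisic acid and osmotic response, 3 of 20 were higher and 0 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.064). AT5G24890 was lower, at -2.58 ± 0.23 (SE, adjusted p = 6.8e-07), at 3.782 ± 1.33 CPM in OX and 23.34 ± 2.5 in WT (SD, n = 3).

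In total 319 genes differed at 6 h, 180 higher and 139 lower in OX, with 84 changed at least 2-fold. After AT5G24890, the next largest decreases within the limits on abundance and overlap were in AT1G77640 (-1.20 ± 0.26), the arabinogalactan protein gene AGP30 (-1.10 ± 0.27), the transporter gene AT2G04050 (-1.01 ± 0.21) and ACS11, of ethylene synthesis (-0.98 ± 0.20, SE), with adjusted p = 0.02, 0.042, 0.017 and 0.015. Each of the 4 calls was lost when 1 or another library was left out, which also costs a replicate. Without WT 6 h replicate 1 adjusted p was 0.16 for AT1G77640, 0.12 for AGP30 and 0.15 for ACS11. Without WT 6 h replicate 2 it was 0.051 for AT1G77640, 0.11 for AGP30 and 0.11 for AT2G04050. Without OX 6 h replicate 1 adjusted p was 0.09 for AT1G77640, 0.3 for AGP30 and 0.09 for ACS11, and without OX 6 h replicate 2 it was 0.067, 0.094 and 0.054 for these and 0.052 for AT2G04050. AGP30 also failed without WT 6 h replicate 3 (0.12) and AT2G04050 without OX 6 h replicate 3 (0.054). Over the alternatives adjusted p ranged from 0.0049 to 0.16 for AT1G77640, 0.0039 to 0.3 for AGP30, 0.00035 to 0.11 for AT2G04050 and 0.00097 to 0.15 for ACS11. PR2 was higher by 1.91 ± 0.36 (SE, adjusted p = 0.0059), which did not pass without WT 6 h replicate 2 (adjusted p = 0.053, range 0.00071 to 0.053). The count of genes was 103, 144 and 192 without WT 6 h replicates 1, 2 and 3 and 134 without OX 6 h replicate 1. It was 574 with DESeq2, 153 with the libraries of 6 h alone, 147 without the 3 libraries of steep length trend and 204 after thinning.

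At 12 h some cysteine-rich receptor-like kinase genes and salicylic acid genes were higher in OX, while most of both lists did not pass. Of 22 of these kinases 7 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 3e-08, adjusted p = 0.33 with an estimated correlation). Of 32 salicylic acid genes 5 were higher and 0 lower (8 and 1 adjusted over the list alone), with a median of 0.09 and a camera adjusted p of 0.0068. That list had adjusted p = 0.43 with an estimated correlation, and 0.051 without WT 12 h replicate 2. Intracellular immune receptors had 1 of 18 higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.8e-05, adjusted p = 0.33 with an estimated correlation). PCR1 was higher by 1.96 ± 0.29 and CYP82C2, an enzyme of indole defence compounds, by 1.68 ± 0.32 (SE, n = 3, adjusted p = 0.00086 and 0.0082). AT5G24890 was lower, at -2.45 ± 0.22 (SE, adjusted p = 2.8e-06). Of 17 phenylpropanoid genes 3 were lower and 0 higher (5 and 0 adjusted over the list alone, camera adjusted p = 4e-05, adjusted p = 0.33 with an estimated correlation). In total 346 genes differed, 194 higher and 152 lower, with 64 changed at least 2-fold. Auxin genes and expansins, more often higher in OX at 1 h, had medians of -0.17 and -0.19 at 12 h. With edgeR 0 of 26 and 0 of 9 passed over all genes (0 higher and 4 lower, and 0 and 1, adjusted over the list alone). Their camera adjusted p values were 8.9e-05 and 0.011, and they had adjusted p = 0.33 and 0.44 with an estimated correlation. The expansin call did not pass without WT 12 h replicate 3 (0.1).

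Several of the largest differences at 12 h did not pass when 1 library was left out. Leaving out a library also costs a replicate, so a lost call need not point to that library. The sucrose carrier gene SUC7 was lower, at -1.94 ± 0.34 (SE, adjusted p = 0.0042), and without OX 12 h replicate 2 its adjusted p was 0.053, the highest in a range from 1.5e-07. The defensin gene PDF1.2A (-2.06 ± 0.40, adjusted p = 0.0087) had adjusted p of 0.056 without WT 12 h replicate 1 and 0.067 without OX 12 h replicate 1, the highest in a range from 9.5e-05. AGP30 (-1.31 ± 0.26, adjusted p = 0.013) had 0.055 and 0.073 without the same libraries, in a range from 7e-05. DIN2 (1.53 ± 0.27, adjusted p = 0.0048) had 0.052 without WT 12 h replicate 1, 0.069 without OX 12 h replicate 2 and 0.063 after thinning, in a range from 1e-04. For PR2 (1.53 ± 0.33, adjusted p = 0.021), adjusted p was 0.088, 0.08 and 0.051 without WT 12 h replicates 1, 2 and 3 and 0.084 and 0.083 without OX 12 h replicates 1 and 3, in a range from 0.00071. AT2G30766 (-1.42 ± 0.32, adjusted p = 0.026) had 0.076, 0.067 and 0.068 without WT 12 h replicates 1, 2 and 3 and 0.12, 0.057 and 0.11 without OX 12 h replicates 1, 2 and 3, in a range from 0.00033. The count of genes at 12 h fell to 118, 146 and 102 without WT 12 h replicates 1, 2 and 3 and to 79, 129 and 121 without OX 12 h replicates 1, 2 and 3. It was 749 with DESeq2 (44.7% higher, against 56.1%), 1018 with the libraries of 12 h alone (41% higher), 562 with the replicate block and 199 without the 3 libraries of steep length trend.

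In WT at 1 h, early defence genes and all low-oxygen genes tested rose against 0 h. WRKY30, a defence transcription factor gene, rose from 0.4455 ± 0.0992 to 114.1 ± 21.3 CPM and the peroxidase gene PER4 from 2.285 ± 0.721 to 254.2 ± 71.3 (SD, n = 3). The log2 fold changes were 7.98 ± 0.18 and 6.85 ± 0.21 (SE, adjusted p = 4e-19 and 2.5e-17). Of 33 early marker genes 31 rose and 1 fell (31 and 1 adjusted over the list alone), with FOX1 at 3.3 ± 0.11 and the ubiquitin ligase gene PUB22 at 3.81 ± 0.14, against ERF104 at -1.28 ± 0.26 (SE). Of 29 pattern recognition genes 27 rose and 1 fell (27 and 1 adjusted over the list alone), including those of the kinases BIK1 (2.55 ± 0.08) and BAK1 (1.64 ± 0.06). All 16 low-oxygen genes tested rose (16 adjusted over the list alone), with PCO2 at 6.05 ± 0.17, PCO1 at 5.76 ± 0.19 and a median of 4.93. Camera adjusted p values were 3.7e-12 for the early markers, 2.9e-12 for pattern recognition and 6.3e-12 for low oxygen, and in that order adjusted p = 0.31, 0.083 and 0.0039 with an estimated correlation.

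Other groups moved at 1 h in WT as well. Of 36 nuclear photosynthesis genes 29 rose and 0 fell (30 and 0 adjusted over the list alone, camera adjusted p = 0.00058, adjusted p = 0.7 with an estimated correlation), such as the light-harvesting gene LHCB1.1 at 1.74 ± 0.20 (SE). Of 15 aliphatic glucosinolate genes 11 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.4 with an estimated correlation). The regulator genes MYB28 and MYB29 fell by 1.35 ± 0.10 and 1.95 ± 0.18. Of 12 heat shock genes 9 fell and 2 rose (9 and 2 adjusted over the list alone), with HSP90.1 at -1.75 ± 0.13 and HSP22.0 at 2.76 ± 0.27. The camera adjusted p of that list was 0.041, with adjusted p = 0.61 with an estimated correlation. It was 0.051 with the replicate block, and 0.054, 0.078 and 0.06 without WT 0 h replicate 2, WT 0 h replicate 3 and WT 1 h replicate 3. Within the limits on abundance and overlap, the largest increases were in the aquaporin gene NIP2;1 (8.31 ± 0.27), WRKY30, CYP82C3 (7.74 ± 0.26), PDC1 (7.24 ± 0.27) and PER4. The largest decreases within these limits were in AT1G07050 (-5.17 ± 0.27), AT5G23240 (-4.01 ± 0.13), JMJD5 (-3.58 ± 0.16), RbcX1 (-3.52 ± 0.20) and CYP706A6 (-3.46 ± 0.25, SE). In total 14244 genes changed, 7402 higher and 6842 lower, of which 3829 changed at least 2-fold. These were 67.8% of the genes tested, with 57.8% at 6 h and 72.5% at 12 h. Scaling by TMM takes most genes as unchanged. The near even split of higher and lower genes and the sign of small changes against 0 h therefore rest on the scaling.

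At 6 h in WT, genes of protein folding and of phenylpropanoid synthesis rose, and those of photosynthesis and jasmonate fell. The receptor-like kinase gene FRK1, a marker of pattern-triggered immunity, rose from 14.57 ± 7.17 to 686.9 ± 71.8 CPM (SD, n = 3), a log2 fold change of 5.55 ± 0.31 (SE, adjusted p = 1.6e-12). EFR, for the receptor of elf18, rose by 1.38 ± 0.08 (adjusted p = 5.1e-12). All 16 endoplasmic reticulum folding genes tested rose (16 adjusted over the list alone), including BIP3 at 4.71 ± 0.21 and ERDJ3B at 1.64 ± 0.08 (SE). Of 17 phenylpropanoid genes 15 rose and 0 fell (15 and 0 adjusted over the list alone), including PAL1 at 2.29 ± 0.14. All 36 photosynthesis genes fell (36 adjusted over the list alone), such as RCA, for Rubisco activase, at -2.02 ± 0.17. Of 27 jasmonate genes 21 fell and 1 rose (21 and 1 adjusted over the list alone), with JAZ9 at -2.82 ± 0.15 and VSP2 at -3.57 ± 0.24. Camera adjusted p values of these 4 lists were 1.3e-09, 1.7e-07, 4.2e-13 and 7e-07, and in that order adjusted p = 0.14, 0.14, 0.34 and 0.23 with an estimated correlation. Cysteine-rich receptor-like kinases had 17 of 22 higher and 2 lower (17 and 2 adjusted over the list alone), with CRK21 at 2.69 ± 0.09 and CRK4 at -2.71 ± 0.29. Low-oxygen genes had 13 of 16 lower and 0 higher (15 and 0 adjusted over the list alone). Their camera adjusted p values were 7e-07 and 1.8e-05, with adjusted p = 0.23 and 0.14 with an estimated correlation. Within the same limits, the largest increases were in the nitrate transporter gene NRT2.5 (6.39 ± 0.21), AT4G12500, AT1G51913, AT2G17740 and AT2G44370, and the largest decreases were in SQP1 (-4.45 ± 0.36), AT3G21670, AT1G14250, FBA5 and the ferric reductase gene FRO7 (-4.02 ± 0.26, SE). In total 12152 genes changed, 6254 higher and 5898 lower, of which 2593 changed at least 2-fold.

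At 12 h in WT, 30 of 32 salicylic acid genes rose and 0 fell (30 and 0 adjusted over the list alone). NIMIN1 rose by 5.84 ± 0.19, SARD4 by 2.81 ± 0.09 and the regulator gene CBP60G by 2.86 ± 0.11 (SE, n = 3). The median was 1.69 and the camera adjusted p 5.7e-11, with adjusted p = 0.14 with an estimated correlation. Of 36 photosynthesis genes 35 fell and 0 rose (35 and 0 adjusted over the list alone). LHCB1.2 stood at 2314 ± 861 CPM at 0 h and 76.05 ± 19 at 12 h (SD, n = 3), a log2 fold change of -4.93 ± 0.25 (SE). Of 17 phenylpropanoid genes 16 rose and 1 fell (16 and 1 adjusted over the list alone), with C4H at 3.59 ± 0.14 and CAD4 at 2.68 ± 0.10 (SE). Of 16 flavonoid genes 11 rose and 0 fell (11 and 0 adjusted over the list alone), with FLS1 at 1.58 ± 0.13. Of 30 tryptophan-derived defence genes 20 rose and 3 fell (20 and 3 adjusted over the list alone), with CYP71A12 at 3.28 ± 0.15 and IGMT1 at -2.43 ± 0.15. For photosynthesis, phenylpropanoid, flavonoid and tryptophan-derived genes the camera adjusted p values were 1.8e-14, 3.4e-09, 0.0077 and 0.00013, and in that order adjusted p = 0.29, 0.16, 0.37 and 0.29 with an estimated correlation. Within the same limits, the largest increases were in the peroxidase genes PER5 (7.95 ± 0.41) and PRX52 (7.39 ± 0.34), AT1G51913, AT3G18250 and AT2G17740. The largest decreases within these limits were in CIPK20 (-7.14 ± 0.30), AT2G15880, the thionin gene AT1G66100 (-6.18 ± 0.48), PIF4, a growth regulator (-5.92 ± 0.20), and LHCB2.3 (-5.91 ± 0.37, SE). In total 15245 genes changed, 7391 higher and 7854 lower, of which 4872 changed at least 2-fold.

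The change against 0 h was then measured within OX, where elf18, the transfer and the time of day again cannot be told apart. At 1 h 14468 genes changed (7390 higher, 7078 lower), at 6 h 12372 (6323 higher, 6049 lower) and at 12 h 14712 (7324 higher, 7388 lower). Of the genes that rose in WT, 81.4%, 80.5% and 86% also rose in OX at 1 h, 6 h and 12 h, and of those that fell 78.4%, 75.3% and 81.4% also fell. That was 6027, 5033 and 6353 genes higher in both genotypes against 2603, 1882 and 2576 for independent lists, and 5363, 4440 and 6392 lower in both against 2304, 1698 and 2761. Both genotypes had the same transfer, peptide and hours and entered a single fit. Independent lists are therefore only a scale here, and the excess is not a test. Heat shock genes rose in OX at 1 h, 11 of 12 (11 adjusted over the list alone, 0 lower), with HSP17.6II at 2.29 ± 0.30 (SE, n = 3, adjusted p = 7.7e-07). The list had a camera adjusted p of 0.0066, with adjusted p = 0.55 with an estimated correlation. Early markers rose in OX at 1 h in 32 of 33 cases (32 adjusted over the list alone). All 16 low-oxygen genes tested rose too (16 adjusted over the list alone, camera adjusted p = 5.1e-10, adjusted p = 0.0095 with an estimated correlation). At 6 h and 12 h low-oxygen genes fell in OX, 15 and 16 of 16 (15 and 16 adjusted over the list alone), with medians of -1.90 and -2.39 and PDC1 at -4.22 ± 0.26 and -4.54 ± 0.26 (SE). Their camera adjusted p values were 3.3e-08 and 1.7e-07, with adjusted p = 0.022 and 0.041 with an estimated correlation. The largest changes in OX within the same limits included WRKY30 (7.75 ± 0.18) and AT1G07050 at 1 h, the aminotransferase gene AT4G28420 and AT1G33055 (-6.40 ± 0.39) at 6 h, and AT4G28420 and CIPK20 at 12 h.

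The interaction asked which changes against 0 h, to elf18, transfer and time of day together, differed between OX and WT. HSFA2, HSP17.6A, HSP17.6II, AT1G07400 and AT1G53540, the last 4 being small heat shock genes, fell in WT and rose in OX at 1 h against 0 h. Their log2 changes were more positive in OX by 4.23 ± 0.30 for HSFA2, 3.60 ± 0.41 for HSP17.6A, 3.51 ± 0.40 for HSP17.6II, 3.3 ± 0.31 for AT1G07400 and 3.18 ± 0.39 for AT1G53540 at 1 h (log2, SE, n = 3 per group, adjusted p = 6.4e-09 for HSFA2). Of 12 heat shock genes the log2 change against 0 h was more positive in OX for 9 and more negative for 0 at each of 1 h, 6 h and 12 h (9 and 2, 9 and 2, and 9 and 0 adjusted over the list alone), with medians of 2.50, 1.81 and 1.54. Of 16 low-oxygen genes it was more negative in OX for 10, 7 and 9 and more positive for 0 (12, 8 and 12 more negative adjusted over the list alone), with medians of -0.88, -0.67 and -1.09. PDC1 was among the largest of these, with -2.81 ± 0.30, -2.90 ± 0.35 and -3.25 ± 0.36 (SE, adjusted p = 1.5e-06, 4.4e-05 and 1.4e-05). The camera adjusted p values at the 3 times were 4.3e-11, 2.3e-08 and 2.2e-09 for heat shock, with adjusted p = 0.038, 0.067 and 0.077 with an estimated correlation. For low oxygen they were 2.1e-07, 1.2e-06 and 6.1e-12, with adjusted p = 0.038, 0.041 and 0.0032 with an estimated correlation.

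The log2 change of abscisic acid and osmotic response genes was more positive in OX for 7, 6 and 6 of 20 at 1 h, 6 h and 12 h and more negative for 0 (8, 11 and 6 more positive adjusted over the list alone). KIN1 differed by 2.41 ± 0.23, 1.92 ± 0.24 and 1.69 ± 0.26 (SE, n = 3 per group, adjusted p = 2.9e-07, 4.5e-05 and 0.00043). The camera adjusted p values were 3.8e-05, 1.3e-05 and 0.0016, with adjusted p = 0.041, 0.041 and 0.14 with an estimated correlation. For expansins it was more positive in OX for 6, 5 and 2 of 9 and more negative for 0 (7, 7 and 4 more positive adjusted over the list alone), with EXPA5 at 1.26 ± 0.14, 0.96 ± 0.14 and 0.73 ± 0.14 (SE). Their camera adjusted p values were 1.7e-07, 5e-07 and 0.0053, with adjusted p = 0.13, 0.15 and 0.55 with an estimated correlation. Of 17 phenylpropanoid genes the change at 6 h was more negative in OX for 7 and more positive for 0 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.4 with an estimated correlation). C4H was at -0.81 ± 0.18 and PAL2 at -0.47 ± 0.10 (SE, adjusted p = 0.0065 and 0.008).

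In total the change against 0 h differed for 2668 genes at 1 h, more positive in OX for 1273 and more negative for 1395. It differed for 1333 at 6 h (720 and 613) and for 1160 at 12 h (645 and 515). A more positive value can be a larger rise or a smaller fall. Of these, 1413, 1049 and 942 also differed between the genotypes at 0 h and not at the later time. Another 420, 89 and 59 differed at the later time and not at 0 h, 261, 43 and 22 at both and 574, 152 and 137 at neither. To differ here means to pass the edgeR test. The interaction subtracts the 0 h difference and more genes passed at 0 h than later, which favours the first of these groups. The counts depended on the 0 h libraries: without WT 0 h replicate 2 they were 1681, 747 and 596. At 6 h the count was 2244 without WT 0 h replicate 1, 775 without WT 6 h replicate 1 and 869 without OX 0 h replicate 3. At 12 h it was 714 without WT 12 h replicate 3, 643 without OX 0 h replicate 3, 737 without OX 12 h replicate 1 and 687 without OX 12 h replicate 2. With only the libraries of the groups compared it was 1659 at 1 h and 691 at 6 h.

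Seedlings hold several organs, so markers of their cells were compared between the genotypes. Of 16 root markers 0 were higher and 1 lower in OX at 0 h (0 and 0 adjusted over the list alone), and 1 and 1 at 1 h (1 and 1 adjusted over the list alone). The numbers were 0 and 0 at 6 h (1 and 2 adjusted over the list alone) and 0 and 1 at 12 h (0 and 2 adjusted over the list alone). The root median was -0.24, -0.02, -0.24 and -0.23 at the 4 times, with camera adjusted p = 0.042, 0.9, 0.02 and 0.0022 and adjusted p = 0.63, 0.95, 0.66 and 0.4 with an estimated correlation. The root hair expansin gene EXPA7 was the lower member at 12 h (-0.73 ± 0.12 SE, n = 3, adjusted p = 0.0027). The nitrate transporter gene NRT2.1 was the higher member at 1 h (1.75 ± 0.22 SE, n = 3, adjusted p = 2.6e-05). The root call at 0 h did not pass without WT 0 h replicate 2 (0.16), WT 0 h replicate 3 (0.21), OX 0 h replicate 1 (0.074) or OX 0 h replicate 2 (0.11). That at 6 h did not pass without WT 6 h replicate 3 (0.22) or OX 6 h replicate 1 (0.12). Of 7 stomatal lineage markers 0 were higher and 1 lower in OX at 0 h (0 and 1 adjusted over the list alone), SPCH at -0.68 ± 0.15 (SE, adjusted p = 0.0034). At 1 h 1 was higher and 0 lower (1 and 0 adjusted over the list alone), TMM at 0.36 ± 0.11 (SE, adjusted p = 0.048). At 6 h and 12 h 0 passed with edgeR (1 and 0, and 1 and 1, adjusted over the list alone). The stomatal median was -0.03, 0.25, 0.04 and 0.16, with camera adjusted p = 0.28, 0.037, 0.28 and 0.77 and adjusted p = 0.63, 0.45, 0.66 and 0.9 with an estimated correlation. The list call at 1 h did not pass without WT 1 h replicate 1 (0.13) or replicate 2 (0.061), or OX 1 h replicate 2 (0.14) or replicate 3 (0.11). The TMM call did not pass without WT 1 h replicate 1 (0.11) or replicate 2 (0.21), or OX 1 h replicate 1 (0.072), 2 (0.075) or 3 (0.086), in a range of 0.0082 to 0.21 over the alternatives.

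Of 5 markers of shoot meristem and epidermis 0 passed at 0 h and 6 h with edgeR (0 and 0, and 1 and 0, adjusted over the list alone). At 1 h and at 12 h 1 was higher and 0 lower (1 and 0 adjusted over the list alone at both), the meristem gene STM at 0.47 ± 0.12 and 0.56 ± 0.12 (SE, n = 3, adjusted p = 0.027 and 0.017). The median was -0.12, 0, 0.01 and 0.1 at the 4 times, with camera adjusted p = 0.31, 0.51, 0.49 and 0.16. The STM call at 1 h did not pass without WT 1 h replicate 2 (adjusted p = 0.12) or OX 1 h replicate 1 (0.15) or with DESeq2 (0.06), in a range of 0.023 to 0.15 over the alternatives. That at 12 h did not pass without WT 12 h replicate 1 (0.096) or replicate 2 (0.072) or OX 12 h replicate 1 (0.097) or replicate 2 (0.064), in a range of 0.012 to 0.11.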

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

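The tests of a single 0 h library, of a genotype effect of constant size, of handling, of linkage, of one shift of all genes, and of length, the shared spread and the 12 h spread in the third pattern were chosen only after the results were seen, and the other uses of the length correction, the steep libraries and thinning only after the data were seen.

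Each value here is a test of the difference between OX and WT in the change against 0 h, and it is listed because the genotypes differed. The number of genes was 2668 at 1 h, 1333 at 6 h and 1160 at 12 h. The heat shock list had a median difference of 2.5 at 1 h. The low-oxygen list had medians of -0.88, -0.67 and -1.09 at 1 h, 6 h and 12 h, and the abscisic acid list medians of 0.42 at 1 h and 0.36 at 6 h. PR1 differed by 1.96 at 1 h and 2.09 at 6 h. Log2 changes at 1 h were more positive in OX for HSFA2 (4.23), HSP17.6A (3.6), HSP17.6II (3.51), AT1G07400 (3.3) and AT1G53540 (3.18), and more negative for the lectin gene AT1G52120 (-3.68), the peroxidase gene AT3G03670 (-3.13), PDC1 (-2.81), DIN2 (-2.74) and AT4G33560 (-2.67). At 6 h they were more positive in OX for HSFA2 (3.34), AT2G28210 (2.78), HSP17.6II (2.56), HSP17.6A (2.53) and AT1G07400 (2.5), and more negative for AT2G01021 (-3.64), AT4G10270 (-3.14), PDC1 (-2.9), LBD41 (-2.82) and AT4G33560 (-2.77). At 12 h they were more positive in OX for HSFA2 (3.2), the alternative oxidase gene AOX1D (2.54), AT1G73602 (2.42), HSP17.6A (2.3) and HSP101 (2.23), and more negative for PDC1 (-3.25), HRA1 (-2.9), AT1G33055 (-2.88), LBD41 (-2.83) and AT4G33560 (-2.79).

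Some of these calls did not pass when 1 library was left out or with only the groups compared in the fit. The 6 h value of AT2G01021 was -0.96 without WT 6 h replicate 1 (adjusted p = 0.34, range 0.0049 to 0.34 over the alternatives). It also did not pass without WT 0 h replicate 2 (0.085), WT 0 h replicate 3 (0.057), OX 0 h replicate 1 (0.055), OX 0 h replicate 2 (0.06), OX 0 h replicate 3 (0.074), OX 6 h replicate 1 (0.1) or OX 6 h replicate 2 (0.068). AT4G10270 did not pass at 6 h without WT 6 h replicate 1 (adjusted p = 0.056) or OX 6 h replicate 1 (0.053), in a range of 5.5e-07 to 0.079. HRA1 did not pass at 12 h without WT 12 h replicate 1 (adjusted p = 0.073) or OX 12 h replicate 2 (0.052), in a range of 6.4e-09 to 0.081. AT1G33055 did not pass at 12 h without WT 12 h replicate 1 (adjusted p = 0.062), WT 12 h replicate 2 (0.06) or OX 12 h replicate 2 (0.061), in a range of 8.1e-07 to 0.12. LBD41 did not pass with only the libraries of the groups compared at 6 h and 12 h (adjusted p = 0.082 and 0.057, ranges 4.8e-08 to 0.082 and 4.6e-08 to 0.057).

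At 0 h most heat shock genes were lower and most low-oxygen genes higher in OX. Most of the interaction calls (1413, 1049 and 942 of them) also passed between the genotypes at 0 h and not at the later time. The interaction subtracts the 0 h difference in the same libraries, and fewer genes passed later. A large share thus follows in part from the design, and not passing later does not show that no difference was left. A single 0 h library as the source is argued against, since at least 9 of the 12 heat shock genes were lower whichever of the 6 was left out, and 9 to 12 low-oxygen genes were higher. Gene length bias is argued against too, with 9 heat shock genes lower and 11 low-oxygen genes higher after the length correction. A genotype effect of the same size at every time would leave no difference between the responses, and the heat shock median of that difference was 2.5 at 1 h. What stays open is a difference in handling or harvest of the 0 h plates. It cannot be told apart from an effect of ELENA1 overexpression that is largest in untreated seedlings, because each genotype was sampled at 1 time before the peptide. Heat shock medians after the transfer were 0.42, -0.47 and -0.32 at 1 h, 6 h and 12 h, and low-oxygen medians -0.15, -0.03 and -0.25. At 12 h the camera adjusted p was 0.0022 for both lists, with adjusted p = 0.4 and 0.33 with an estimated correlation.

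The second pattern is a set of 21 genes that differed in the same direction at all 4 times, 18 higher and 3 lower in OX. If the 4 lists were independent, 0.0437 genes would be called at all 4 times in any direction, so fewer in the same direction. Linkage to a single changed region is argued against for the set, since the genes lie on 5 chromosomes and 2 of them are within 5 tested loci of another, a number that 95% of 10000 random sets did not exceed. Library size factors are argued against only as the sole cause of the whole set. A wrong factor moves every gene of a library alike, and the fold changes of the 18 higher genes differed beyond their SE at each time (chi-square per degree of freedom of at least 7.5). Part of that spread may come from the choice of genes, since a gene with a larger SE needs a larger fold change to pass. A shift added to unequal genotype effects was not tested. With RLE 19 of the 21 were called in the same direction at all 4 times, though RLE is no strong test, since its largest move of the median was -0.0146, at 12 h. A hypothesis that these genes follow ELENA1 level stays open, as does a second difference between the lines, because the labels tell no separate overexpressing lines apart and each time holds the same 2 genotypes.

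The third pattern is the smaller number of genes that differed between the genotypes at 6 h (319) and 12 h (346) than at 0 h (3072). Genes with an unadjusted edgeR p under 0.05 numbered 5680 at 0 h, 2995 at 6 h and 4372 at 12 h. The gap at 12 h is thus much smaller before adjustment, and its size depends on the threshold. The size of the pattern at 12 h also depends on which libraries enter the fit. With only the libraries compared the numbers were 1889 at 0 h and 1018 at 12 h. At 6 h the number was 153, so the gap stayed there. That alternative redoes the filter, the size factors and the spread together, so a spread estimated over all groups was not tested on its own. With all groups in the fit, unequal depth and a trend with transcript length are argued against as the whole cause. The numbers at 6 h and 12 h were 204 and 275 against 2576 after thinning to the smallest total. After the length correction, which keeps the 3 steep libraries, they were 434 and 363 against 3686. Leaving those libraries out gave 147 and 199 against 3936. That takes replicates from 6 h and 12 h but not from 0 h, so it cannot test the steep libraries. Leaving out any 1 library of those times gave as few as 103 and 79. A larger spread between replicates is argued against at 12 h, where the median SD of log2 CPM was 0.125 in WT and 0.088 in OX against 0.132 and 0.096 at 0 h, a difference of at most -0.007. Open are a smaller genotype effect after elf18, the handling of the 0 h plates and, at 6 h, the spread in OX (0.159).

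Other groupings of the same libraries were tried for every count. For each comparison of 3 libraries with 3, 10 splits are too few for a share under 0.05, and in each the real split was the 1 with the most genes. For OX against WT the real counts were 3072, 1197, 319 and 346, and the highest of the other splits 6, 0, 0 and 0. For elf18 in WT they were 14244, 12152 and 15245 against 68, 2 and 0, and for elf18 in OX 14468, 12372 and 14712 against 0, 0 and 0. For the interactions 30 groupings were drawn. At 1 h 1 of the 30, the real one, gave 2668 genes and the highest other 1235. That share is under 0.05 but rests on few groupings and was not adjusted over the 3 interactions. It argues against chance at 1 h without excluding it. At 12 h 1 of the 30, the real one, gave 1160, but the highest other gave 1138. Leaving out single libraries moved the real count there from 596 to 1705, so the 12 h result is not firm. Chance cannot be excluded at 6 h, where 3 of the 30 gave as many as the real 1333 and the highest other gave 1904. The genotype labels were exchanged within each time on its own. A grouping could therefore keep the genotypes apart at 0 h and carry that difference. Such groupings are not free of a genotype effect, so at 6 h and 12 h the test does not decide.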

How the results depend on the processing

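The removal of length trends, leaving out the 3 steep libraries and thinning were tests chosen only after the data were seen. Counts that moved more than 1.5 times were, for OX against WT at 0 h, 1889 with only the libraries compared. At 1 h they were 502 with those libraries and 612 without the steep ones. At 6 h they were 574 with DESeq2, 153 with only the libraries compared, 147 without the steep ones and 204 thinned. At 12 h they were 749 with DESeq2, 562 with the replicate block, 1018 with only the libraries compared and 199 without the steep ones. Interaction counts with only the libraries compared were 1659 at 1 h and 691 at 6 h. The cause was not tested for any of these moves. The 6 counts against 0 h within a genotype stayed within 1.5 times of their values under every alternative run.

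Leaving out each library in turn gave 1825 to 3578 genes for OX against WT at 0 h, 472 to 1162 at 1 h, 103 to 370 at 6 h and 79 to 146 at 12 h. For WT it gave 12971 to 13903, 10814 to 12056 and 14386 to 14775 at 1 h, 6 h and 12 h, and for OX 13168 to 14125, 11033 to 12331 and 13684 to 14128. For the interactions it gave 1681 to 3299, 747 to 2244 and 596 to 1705.

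Of 24634 alternative values of named genes, 23083 kept direction and side of the threshold, 1193 no longer passed, 265 newly passed, 84 changed sign without having passed and 9 that had passed reversed. The 9 came with the length correction: ATML1 0.15 in WT at 1 h and 0.37 and 0.10 in OX at 1 h and 6 h, and MED13 0.25 in WT at 12 h and 0.34 in OX at 1 h. The rest were SPK1 0.19 in WT and 0.18 in OX at 12 h, and PEPR2 0.11 and CHS3 0.27 in OX at 1 h. The correction subtracts a trend with length from every gene, and its effect on these was not tested further. Of the list tests, 135 no longer passed with an estimated correlation and 177 were the same. Most of those 177 had passed with neither correlation, so most list calls were lost. Calls that passed with both were only of the heat shock, low-oxygen and abscisic acid lists. RLE moved the median fold change of all genes by at most 0.0255. Like TMM it takes most genes as unchanged, so it does not test that assumption for the comparisons with 0 h. DESeq2 gave no adjusted p for 410 genes in each of the interactions at 1 h and 12 h.

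Replicate numbers were not taken to pair libraries, because not every pair with the same number correlated over 0.1. Over 84 such pairs the correlation of deviations ran from -0.341 to 0.544 with a median of 0.0506, and 33 were over 0.1. As a hint of some shared structure, 15 of 24 libraries were closest to their own number, and replicate 3 had the lowest total count of every group. A batch by replicate number is therefore not excluded, and the main fit holds no term for it. Besides the 12 h count of OX against WT, the replicate block moved no count over 1.5 times, and of the list tests it ended 1 call and added 1. The FPKM alternatives were not run, since there is 1 column per group, nor was removal of organelle loci, as there were 0. Depth limits genes of low count most in replicate 3 of each group.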

Other observations

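The tests of the set of 21 genes and the simulated overlaps were chosen only after the results were seen, and the others were fixed before. Time-of-day genes changed in WT against 0 h, where elf18, the transfer and the time of day cannot be told apart. Of 24 clock genes 8 rose and 14 fell at 1 h (8 and 14 adjusted over the list alone). At 6 h 6 rose and 15 fell (6 and 15 adjusted over the list alone) and at 12 h 7 rose and 14 fell (7 and 14 adjusted over the list alone). FKF1, a blue light receptor gene, fell by 2.98 ± 0.12 at 1 h while the morning gene LHY changed by 2.90 ± 0.15, and PRR7 changed by -4.15 ± 0.16 at 12 h (SE, n = 3). The camera adjusted p values were 0.16, 0.025 and 0.023, and adjusted p = 0.61, 0.34 and 0.29 with an estimated correlation, and the 6 h call did not pass without WT 0 h replicate 3 (0.058). Between the genotypes at 0 h, 6 of 24 clock genes were higher and 6 lower in OX (8 and 6 adjusted over the list alone), with TOC1 at 0.54 ± 0.07 and PRR9 at -1.69 ± 0.23 (SE), and a camera adjusted p of 1. Of 13 cell cycle genes 6 rose and 0 fell in WT at 6 h (6 and 0 adjusted over the list alone, camera adjusted p = 0.092), with HINKEL at 0.91 ± 0.16 (SE). Of 19 Mediator subunits 7 rose and 7 fell in WT at 1 h (7 and 7 adjusted over the list alone, camera adjusted p = 0.94). Of these, 1 was higher and 0 lower in OX than in WT at 0 h (0 and 0 adjusted over the list alone, camera adjusted p = 0.25). At 1 h 0 were higher and 1 lower (0 and 4 adjusted over the list alone), CDK8 at -0.41 ± 0.11 (SE, adjusted p = 0.029), with a camera adjusted p of 0.031 and adjusted p = 0.45 with an estimated correlation. The list call did not pass without OX 1 h replicate 1 (0.16). The CDK8 call did not pass without WT 1 h replicate 3 (adjusted p = 0.18), OX 1 h replicate 1 (0.25) or OX 1 h replicate 2 (0.065), in a range of 0.0088 to 0.25 over the alternatives. At 6 h 0 and 0 Mediator subunits passed with edgeR and at 12 h 1 and 0 (0 and 0, and 1 and 0, adjusted over the list alone), with camera adjusted p values of 0.99 and 0.16.

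Photosynthesis genes had medians of 0.29 and 0.22 in OX against WT at 1 h and 6 h, with 0 of 36 passing at either time with edgeR over all genes or adjusted over the list alone. Their camera adjusted p values were 2.4e-05 and 8.8e-06, with adjusted p = 0.48 and 0.66 with an estimated correlation. At 12 h their median was -0.12, again with 0 of 36 passing over all genes or adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.81 with an estimated correlation). That call did not pass without WT 12 h replicate 3 (0.57). At 1 h 3 of 12 heat shock genes were higher and 1 lower in OX (4 and 1 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.031, adjusted p = 0.45 with an estimated correlation). That list call did not pass without WT 1 h replicate 1 (0.13) or replicate 3 (0.098) or OX 1 h replicate 2 (0.32). At 6 h 0 of 12 heat shock genes passed (0 higher and 3 lower adjusted over the list alone), with a median of -0.47 (camera adjusted p = 3.5e-05, adjusted p = 0.34 with an estimated correlation).

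Among the 21 genes that differed in the same direction at all 4 times, singled out after their values were seen, were the MADS box genes MAF5 and MAF4, which delay flowering and stand next to each other. MAF5 was lower in OX, with log2 fold changes of -3.11, -2.42, -2.41 and -2.12 at 0 h, 1 h, 6 h and 12 h, with adjusted p = 3.1e-09, 3.3e-07, 3.8e-07 and 3.6e-06. It stood at 0.443 ± 0.165 CPM in OX and 3.459 ± 0.434 in WT at 0 h (SD, n = 3). MAF4 differed by -0.98, -1.11, -0.88 and -0.97, with adjusted p = 0.0025, 0.0029, 0.043 and 0.022. The 6 h call of MAF4 did not pass without WT 6 h replicate 1 (adjusted p = 0.15), replicate 2 (0.17) or replicate 3 (0.082), or OX 6 h replicate 2 (0.12) or replicate 3 (0.09), in a range of 0.0045 to 0.21 over the alternatives. Its 12 h call did not pass without WT 12 h replicate 1 (0.082), replicate 2 (0.076) or replicate 3 (0.052), or OX 12 h replicate 2 (0.13) or replicate 3 (0.083), in a range of 0.0015 to 0.13. The nearby genes MAF3 and AGL31 were at 0.29 and 0.16 at 0 h (adjusted p = 0.032 and 0.34). AT3G28510 was higher by 2.05, 2.85, 4.18 and 1.56, and the U-box kinase gene AT3G49060 by 1.48, 0.66, 1.23 and 1.04.

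Fold changes of OX against WT at 0 h and of elf18 in WT at 1 h, 6 h and 12 h share the WT libraries of 0 h. Across 21015 genes, which are not independent replicates, r was 0.295, 0.126 and 0.129, against 0.462, 0.48 and 0.463 in 50 simulations of unchanged groups against those controls. The covariance was 0.0993, 0.0352 and 0.049 against simulated values of 0.0143, 0.0143 and 0.0142. The differences were 0.085, 0.0209 and 0.0348, with no SE of their own. The simulations hold no shift common to the WT libraries of 0 h, so these differences are not read as a shared effect. The SE of r from leaving out libraries was 0.08, 0.171 and 0.117. At 1 h 992 genes were higher in both lists against 570 for independent lists and 755 lower in both against 473, at 6 h 415 against 482 and 679 against 408, and at 12 h 527 against 569 and 654 against 543. Genes higher in OX and lower with elf18 numbered 261 against 527 at 1 h, 756 against 454 at 6 h and 757 against 605 at 12 h, and those lower in OX and higher with elf18 371 against 512, 309 against 432 and 459 against 511. For OX against WT at 1 h, 6 h or 12 h and elf18 at another time, which share no libraries, r ran from -0.158 to 0.174. Independence is not the value without a shared effect here, since both lists hold the WT libraries of 0 h. In 20 simulations of unchanged groups each of these overlaps was 0 genes, a value that leaves out the effects, so the excess over either is not read as a shared effect. With 3 libraries the controls cannot be divided into parts of at least 2, so some of the excess may come from the shared controls (r at 1 h was 0.297 with no filter on counts).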
